A study of Etheostoma caeruleum and Etheostoma flabellare and Etheostoma blennioides with 48 samples.

How the data were processed

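Liver mRNA was profiled in 48 wild fish of 4 darter species, small bottom-living fishes of the genus Etheostoma: rainbow darter (E. caeruleum), fantail darter (E. flabellare), greenside darter (E. blennioides) and johnny darter (E. nigrum). For each species, 6 fish came from upstream and 6 from downstream of a municipal wastewater outfall on the Grand River in Ontario. Per the labels' protocols, RNA was extracted with QIAzol and chloroform and polyadenylated RNA was made into directional libraries. Trimmomatic 0.36, Bowtie2 2.2.7 and RSEM 1.3.1 are named in the submitters' processing notes. Their options, the strand setting and any filters are not given in the sources used here.

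The authors deposited estimated counts per gene for each species, in a separate table for each. The authors also deposited TPM, which sum to the same value in every library, of the same genes. The row identifiers have the form that the assembler Trinity writes, and each species has its own set of rows. There were 384271 rows in rainbow, 445800 in fantail, 401838 in greenside and 362394 in johnny darter. Each row is called a gene below. Several rows may belong to 1 gene of the fish, which could not be told here. The files do not pair these identifiers with gene names, so rows could not be matched between species. No reference genome or annotation was used here. The deposited estimated counts equal TPM rescaled to the total of each library: between 99.987% and 99.989% of values divided by that scale were within 0.01 of TPM. They are therefore TPM scaled to each library's total, and 1 read of a short gene is worth more than 1. The smallest positive values were 0.41 to 0.53. A count model treats these values as read counts, which they resemble only in total, and the fixed design had assumed RSEM expected counts, so the precision it assigns to low and short genes is approximate.

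Estimated counts were rounded to whole numbers. Genes were tested in each species separately with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test, TMM normalization and filterByExpr with a minimum count of 10 and a minimum total of 15. Adjusted p-values are Benjamini-Hochberg values over the genes tested (fewer with DESeq2, as given below), with a threshold of 0.05 and no fold limit. The filter kept 85736 genes in rainbow, 85868 in fantail, 90942 in greenside and 81244 in johnny darter, holding 96.7% to 97.5% of counts. Standard errors of log2 fold changes were computed as the size of the fold change divided by the square root of its F statistic. The share of variance between fish explained by site was computed on squared distances of TMM-normalized log2 CPM (prior count 2), with an exact one-sided permutation test over the 462 splits of 12 fish into groups of 6. Spread was the mean distance of each fish to the centre of its site. Single values per library were compared by exact two-sided permutation tests over 924 assignments. Spread was compared two-sided over the same number of assignments of the distances. The centres of the real sites were kept, so that test is not exact. The smallest p that these tests can give is 0.0022. These p-values were adjusted over the 4 species. Differences between species in a site effect were tested by permuting species within site after centring each species (1e+05 resamples), adjusted over 6 pairs.

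Genes named by identifier followed a rule set before the data were examined. At most 2 that rose and 2 that fell were taken per species, those with the smallest p past the threshold. They also needed a mean CPM of at least 1 and complete separation of the 6 downstream from the 6 upstream values, a condition waived where no gene met it. The alternatives were RLE and upper quartile normalization, no filter, CPM of at least 1 in 6 libraries, robust estimation, DESeq2 1.42.0, limma 3.58.1 (voom with library weights, and limma-trend on log2(TPM + 1)), the replicate number as a block, 1 surrogate variable from sva 3.50.0, a fold of at least 2 and each library left out. A filter of CPM of at least 5, DESeq2 and limma-trend with the filter of CPM of at least 1, each library left out of the share of counts in the 100 most abundant genes, and further left-out fish and a covariate in fantail darter were chosen after seeing the data. Values on log2(TPM + 1), including those given to limma-trend, were not normalized between libraries, unlike those of the other settings. At the filter used, DESeq2 gave no adjusted p to 266 genes in rainbow, 32032 in fantail, 40717 in greenside and 16174 in johnny darter. Its adjusted p-values are therefore over fewer genes than those of edgeR. Gene lists and agreement between species had been planned and could not be computed without gene names.

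The quasi-likelihood fit was tested on simulated data with 200 changed genes per species, drawn as independent negative binomial counts. Such counts do not check the fit on scaled TPM or with many more changed genes. At the filter used, it found 7.46% of genes changed 2-fold in rainbow, 0% in fantail, 2.99% in greenside and 0% in johnny darter. For 4-fold changes it found 26.9%, 14.9%, 17.9% and 19.4%, and for 16-fold changes 65.2%, 50.0%, 60.6% and 56.1%. No simulated change was called in the wrong direction, and 1 to 4 unchanged genes were called per species. At a CPM of at least 1 in 6 libraries, it found 68.7%, 61.2%, 50.7% and 52.2% of 4-fold changes. There, 3 to 7 unchanged genes were called per species. The permutation tests were checked on 1500 simulated data sets of independent normal values without any difference. The test of variance called 5.33% and the test of spread 7.87% at an unadjusted p under 0.05, so the test of spread is somewhat liberal. These rates need not hold for real genes, which vary together. Figures were drawn with matplotlib 3.10.9.

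Library totals ranged from 40.9 to 82.7 M estimated counts. No 2 libraries held identical values. The titles call the fish biological replicates. The sex of the fish is not given in the sources used here, and no sample was left out.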

Results

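The data were liver transcript levels of 48 fish, 6 per site for each of 4 darter species. The question the design addresses is how the liver transcriptome of fish living downstream of a wastewater outfall differs from that of fish living upstream. The labels name 2 sites, so p-values measure the spread between fish. An effect of the outfall cannot be told apart from any other difference between the sites. Totals were 52.7 to 67.6 M estimated counts in rainbow darter, 40.9 to 55.3 in fantail darter, 45.6 to 70.7 in greenside darter and 47.6 to 82.7 in johnny darter. Totals did not differ by site past the threshold in any species (adjusted p = 0.12 to 0.31, exact permutation tests). Each library listed between 143981 and 223360 genes above 0, and between 34592 and 60785 at 1 TPM or more. A gene here is 1 row of an assembly, and several rows may belong to 1 gene of the fish. Pearson correlations of log2(TPM + 1) between fish of the same species, computed across genes that reached 5 TPM in any fish, ranged from 0.66 to 0.92. Genes are given by assembly identifier, since the files do not pair rows with gene names.

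In johnny darter, 28 genes changed between sites: 22 were higher and 6 were lower downstream. Of the 22, 12 had values at both sites, and these were 2.69-fold to 15.8-fold higher downstream (median 3.73-fold), with all 6 downstream fish above all 6 upstream fish. The remaining 10 were listed at 0 in all 6 upstream fish, with downstream means of 0.28 to 1.75 TPM. All 6 genes that were lower were listed at 0 in all 6 downstream fish, with upstream means of 0.38 to 1.68 TPM. TRINITY_DN13054_c2_g1 rose from 9.12 ± 1.45 TPM (SD, n = 6) upstream to 42.2 ± 16.3 TPM (SD, n = 6) downstream. Its log2 fold change was 2.23 (SE 0.26, edgeR quasi-likelihood adjusted p = 0.046). TRINITY_DN3173_c0_g3 rose from 2.605 ± 1.13 TPM (SD, n = 6) to 12.5 ± 1.85 TPM (SD, n = 6). Its log2 fold change was 2.27 (SE 0.28, edgeR adjusted p = 0.046). Complete separation arises by chance in 0.216% of assignments, or about 175.9 of the 81244 genes tested, and it was a condition for naming a gene rather than evidence for it. Adjusted p-values of the 28 genes lay between 0.046 and 0.049, close to the threshold. Leaving out any 1 of the 12 fish reduced the count to 0 or 1, and DESeq2 called 621 genes (405 higher, 216 lower). Without a filter, with robust estimation or with 1 surrogate variable edgeR called 0 genes, at a CPM of at least 1 it called 5, and limma-voom called 1. Limma-trend on TPM called 28 genes, of which 19 were among those called by edgeR.

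**Figure D1:**
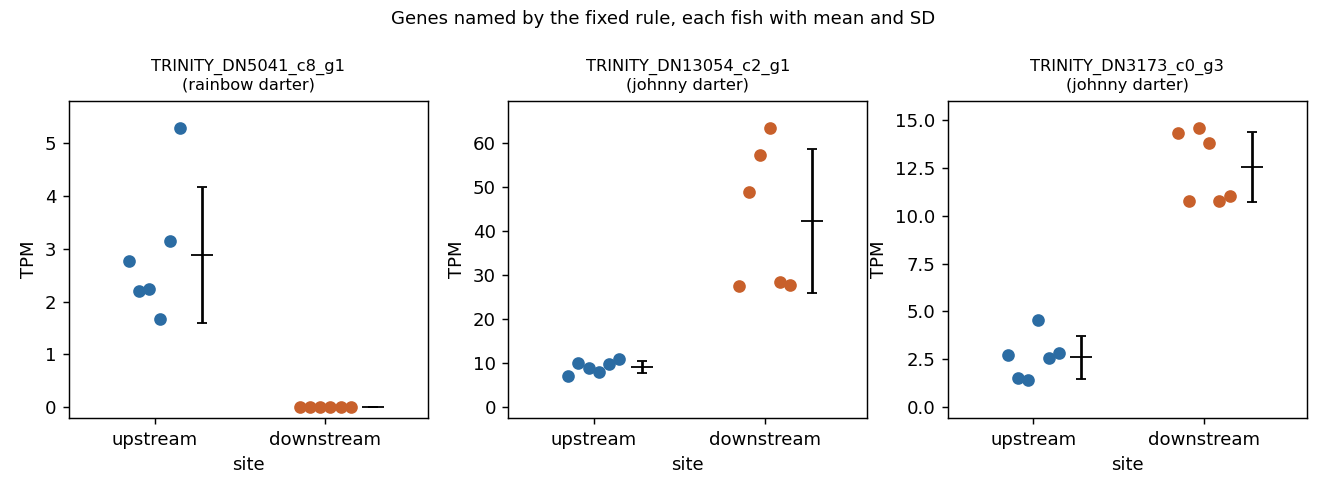
TPM of the 3 genes named by the fixed rule in each fish (points), by site, with the mean and SD of 6 fish beside them. The johnny darter gene TRINITY_DN13054_c2_g1 lay between 6.98 and 10.9 TPM upstream and between 27.6 and 63.4 TPM downstream.

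In rainbow darter, 1 gene changed, and it was lower downstream. TRINITY_DN5041_c8_g1 was listed at 0 in all 6 downstream fish and between 1.67 and 5.28 TPM in the 6 upstream fish (edgeR quasi-likelihood adjusted p = 0.045). At an unadjusted p under 0.05 there were 3041 genes, where 5% of those tested is 4287 and the median over other drawn splits of the same fish was 2248. DESeq2 called 111 genes, limma-trend on TPM called 4 and limma-voom called 0. The call was lost when any fish but downstream fish 2 was left out, and 2 genes were called without that fish.

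In fantail darter, no gene passed the threshold with edgeR at the filter used, while 15432 of 85868 genes lay at an unadjusted p under 0.05, where 5% is 4293 and the median over other drawn splits was 2112. Restricted to 39928 genes with a CPM of at least 1 in 6 libraries, edgeR called 2129 genes, 876 higher and 1253 lower downstream. Their median absolute log2 fold change was 0.97. The smallest adjusted p among them was 0.042, close to the threshold. The count was 0 to 4 without any 1 of 7 fish (upstream 2, 4 or 5, downstream 2, 4, 5 or 6), although 9323 to 10538 genes still lay at an unadjusted p under 0.05, against 11979 with all fish. It was 4178 without downstream fish 1 and 3641 without downstream fish 3. DESeq2 called 9140 genes (3363 higher, 5777 lower), limma-voom 1542 (475 higher, 1067 lower) and limma-trend on TPM 6463 (6152 higher, 311 lower). The balance of directions differed between tools and filters: at a CPM of at least 5 edgeR called 1541 higher and 1506 lower, and at a CPM of at least 1 DESeq2 called 3819 higher and 4059 lower. Limma-trend was run on TPM without normalization between libraries, so its balance carries the shift of unscaled TPM given next. Over the genes with a CPM of at least 1, the median log2 difference was 0.06 after TMM normalization and 0.35 on unscaled TPM, and 53.3% and 72.2% of genes, respectively, were higher downstream. Without downstream fish 1, edgeR called 1007 genes at the filter used.

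In greenside darter, no gene passed the threshold with edgeR, and 8174 of 90942 genes lay at an unadjusted p under 0.05, where 5% is 4547 and the median over other drawn splits was 2324. DESeq2 called 2343 genes (1582 higher, 761 lower), limma-trend on TPM 35 (3 higher, 32 lower) and limma-voom 0. The median log2 difference over genes with a CPM of at least 1 was -0.03 after TMM normalization and -0.20 on unscaled TPM, the scale limma-trend was run on. Leaving out downstream fish 1 gave 1 gene.

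Site explained part of the variance between fish in 3 of the species. Its share was 15.7% in fantail darter, 11.6% in greenside darter and 10.9% in johnny darter (adjusted p = 0.0043, 0.0087 and 0.0043, exact one-sided permutation tests). On log2(TPM + 1) the fantail darter share was 25.2%. The median over all splits of the same fish was 8.6%, 9.0% and 9.0%. In rainbow darter the share was 9.14%, with a median over splits of 9.0% (adjusted p = 0.36, exact permutation test). On the 1000 most variable genes the shares in greenside and johnny darter, 9.36% and 10.1%, no longer passed the threshold (adjusted p = 0.31 and 0.074, exact permutation tests). Whether the shares differ between species was not tested. The mean TMM factor was 0.86 upstream and 1.18 downstream in fantail darter, and 1.08 and 0.93 in greenside darter. Both differences gave an adjusted p of 0.0087 (exact permutation tests). It did not differ past the threshold in rainbow or johnny darter (adjusted p = 0.93 for both, exact permutation tests). In fantail and greenside darter, the shares therefore cannot be told apart from a difference in library composition between sites.

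**Figure D2:**
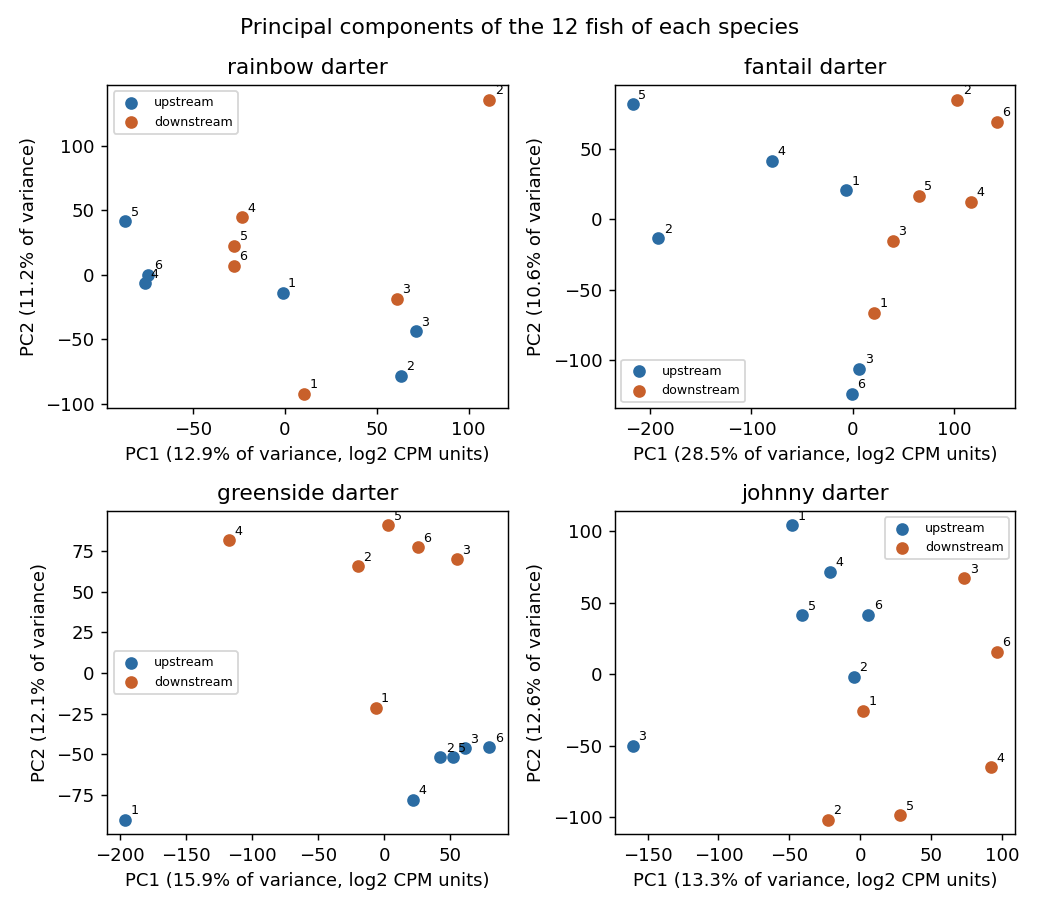
Scores of the 12 fish of each species on the first principal components of log2 CPM over genes with a CPM of at least 1 in 6 libraries, with the percent of variance on each axis, coloured by site and numbered by replicate. Fantail darters of the 2 sites did not overlap on the PC1 axis (28.5% of variance), and greenside darters did not overlap on the PC2 axis (12.1%). On the fantail darter PC1 axis, upstream fish 5 and 2 (TMM factors 0.74 and 0.71) lay at one end and downstream fish 6 (1.34) at the other. Site therefore cannot be told apart from library composition on that axis.

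The most abundant transcripts took a smaller part of the fantail darter liver transcriptome downstream and a larger part of that of greenside darter. In fantail darter, the 100 most abundant genes of each library held 33.3% ± 2.39 (SD, n = 6) of counts upstream and 25.5% ± 3.63 (SD, n = 6) downstream (adjusted p = 0.017, exact permutation test). In greenside darter they held 29.6% ± 1.90 (SD, n = 6) upstream and 32.4% ± 1.36 (SD, n = 6) downstream (adjusted p = 0.043, exact permutation test). In johnny darter the shares were 32.99% ± 1.36 and 31.2% ± 1.45 (SD, n = 6 each), and in rainbow darter 35.8% ± 0.93 and 35.2% ± 1.48 (SD, n = 6 each). Neither difference passed the threshold (adjusted p = 0.075 and 0.41, exact permutation tests). The greenside darter call was lost when any 1 of 8 of its 12 fish was left out, with differences of 2.198 to 3.22 percentage points over all 12 and adjusted p up to 0.075.

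**Figure D3:**
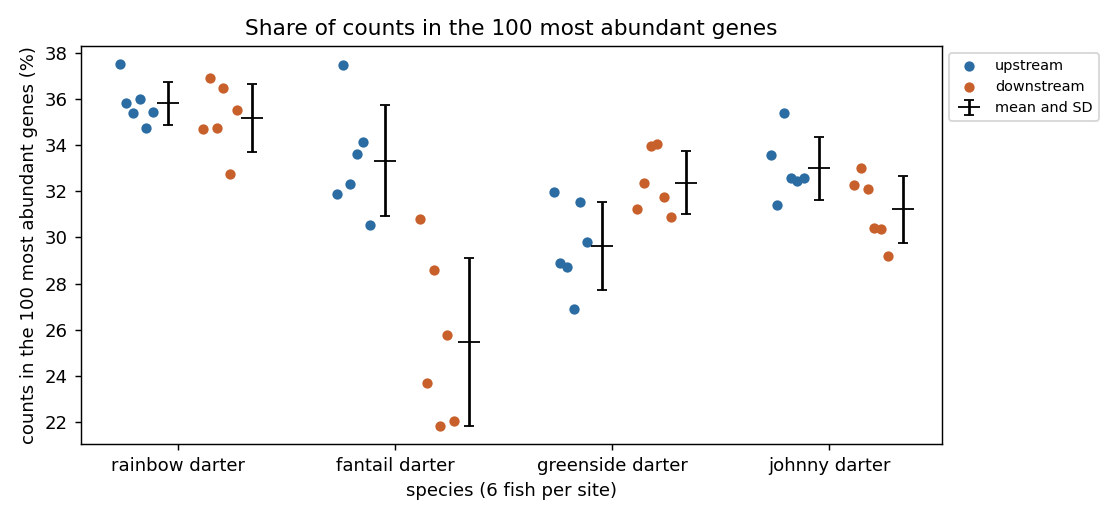
Percent of each library's counts held by its own 100 most abundant genes, for each fish (points) with the mean and SD of 6 fish, by species and site; the vertical axis does not start at 0. Fantail darter means were 33.3% upstream and 25.5% downstream.

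The number of genes listed above 0 moved the opposite way. In fantail darter it was 170176 ± 13510 (SD, n = 6) upstream and 201596 ± 17907 (SD, n = 6) downstream. In greenside darter it was 198999 ± 7875 (SD, n = 6) upstream and 170956 ± 8326 (SD, n = 6) downstream. Both differences gave an adjusted p of 0.0087 (exact permutation tests). For genes at 1 TPM or more, neither difference passed the threshold. Means were 43511 upstream and 50987 downstream in fantail darter, where upstream fish 5 alone had 60785 (adjusted p = 0.16, exact permutation test). In greenside darter they were 48816 and 44210 (adjusted p = 0.061, exact permutation test). Differences in rainbow and johnny darter did not pass the threshold (adjusted p = 0.92 and 0.74, exact permutation tests).

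**Figure D4:**
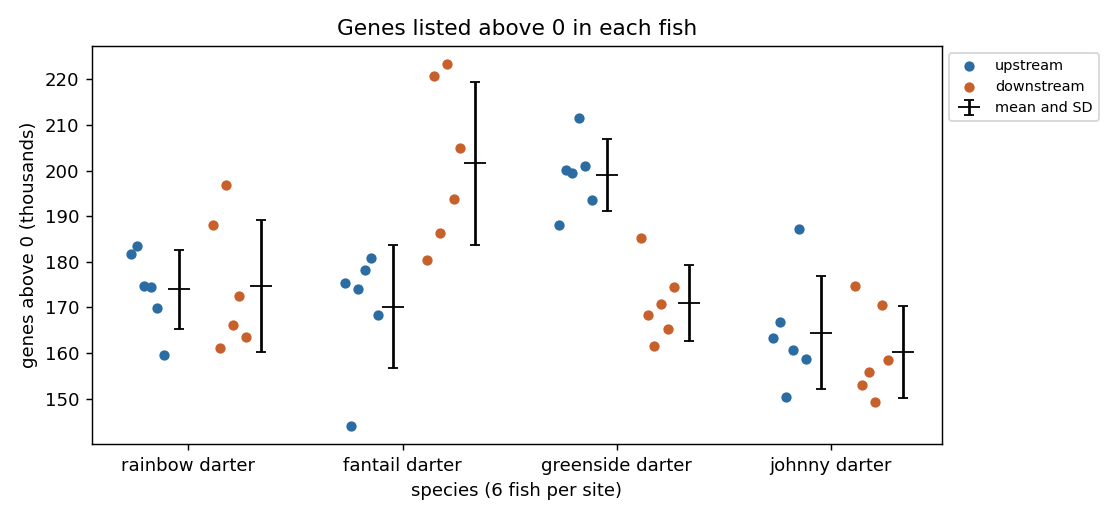
Genes listed above 0 in each fish, in units of 1000 (points), with the mean and SD of 6 fish, by species and site; the vertical axis does not start at 0. Greenside darter means were 198999 genes upstream and 170956 downstream.

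Fish differed from each other less downstream in fantail darter and more downstream in greenside darter on log2 CPM. TMM factors also differed by site in these species, so an effect of site on spread cannot be told apart from library composition. The mean distance of a fish to the centre of its site fell from 391.9 to 340.9 in fantail darter and rose from 354.8 to 406.9 in greenside darter (adjusted p = 0.0087 and 0.026, permutation tests). The test of spread is somewhat liberal, calling 7.87% of simulated data sets without a difference at an unadjusted p under 0.05. The mean distance was 366.8 and 372.9 in rainbow darter, and 357.2 and 372.1 in johnny darter (adjusted p = 0.34 and 0.19, permutation tests). On the 1000 most variable genes neither call was kept, with differences of -4.40 in fantail and 4.16 in greenside darter (adjusted p = 0.42 for both, permutation tests). On log2(TPM + 1) the fantail darter difference changed sign, to 12.03, and that of greenside darter was 0.73 (adjusted p = 0.28 and 0.94, permutation tests). The greenside darter call was lost without upstream fish 2, 3, 4 or 5, and without upstream fish 3 johnny darter passed the threshold with a difference of 24.01 (adjusted p = 0.0043, permutation test).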

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

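The tests of fantail darter upstream fish 5 were chosen after its values were seen. Outlying fish were sought in 56 comparisons, each of 1 measure among the 6 fish of a species and site. Chance flags about 1 in 20, or 3, and 6 were found. Several related measures came from the same fish, so the comparisons are not independent and 6 against 3 is no test of an excess. Johnny darter upstream fish 5 had 82.7 M estimated counts, against 52.7 to 61.9 M in the other 5. Fantail darter upstream fish 2 listed 143981 genes above 0, against 168386 to 180907 in the others of its group. Rainbow darter upstream fish 4 lay nearest to the centre of its site, at 354.0 against 365.4 to 371.9, and greenside darter upstream fish 1 lay farthest, at 426.5 against 332.4 to 360.2.

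Fantail darter upstream fish 5 listed 60785 genes at 1 TPM or more, against 34592 to 42388 in the other 5 upstream fish, and 6.17% of its counts fell in genes seen in no other fantail darter, against 0.28% to 0.35% in those 5. There were 51475 such genes, with a median of 1.03 TPM and a maximum of 48.8 TPM. Deeper sequencing is argued against, since its total of 47.9 M was below the median of 50.996 M of the other 11 libraries. Transcripts of another organism or cell type may be the source and stay open: the 100 highest of these genes held 2.27% of their counts, and a low share excludes nothing because abundant conserved transcripts can join rows of the host. No biological explanation was tested.

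The effect of site on the share of counts in the 100 most abundant genes differed between species in 5 of 6 pairs by permutation. The fantail darter effect of -7.87 percentage points was lower than those of rainbow, greenside and johnny darter; the difference rainbow minus fantail was 7.23 (adjusted p = 0.0025), fantail minus greenside was -10.6 (adjusted p = 0.00036) and fantail minus johnny was -6.10 (adjusted p = 0.0069). The greenside darter effect of 2.75 points was higher than the others, with a difference of rainbow minus greenside of -3.38 (adjusted p = 0.0098) and of greenside minus johnny of 4.51 (adjusted p = 0.0025). Rainbow and johnny darter did not differ past the threshold (difference 1.14, adjusted p = 0.29).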

How the results depend on the processing

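A CPM of at least 5, DESeq2 and limma-trend at a CPM of at least 1, and leaving out each fish from the share of counts were chosen after seeing the data. The cause of the changes below was not tested. DESeq2 gave no adjusted p to part of the genes, so its counts are not over the same genes as those of edgeR. Genes changed in rainbow darter (1) became 2 at a CPM of at least 1, 111 with DESeq2, 80 with DESeq2 at that CPM, 4 with limma-trend, 3 with limma-trend at that CPM, 0 with limma-voom and 0 with 1 surrogate variable; leaving out each fish gave 0 to 2. In fantail darter (0) they became 2129 at a CPM of at least 1, 3047 at a CPM of at least 5, 9140 with DESeq2, 7878 with DESeq2 at a CPM of at least 1, 1542 with limma-voom, 6463 with limma-trend, 6832 with limma-trend at that CPM and 1 with 1 surrogate variable; leaving out each fish gave 0 to 1007. In greenside darter (0) they became 2343 with DESeq2, 1926 with DESeq2 at a CPM of at least 1, 35 with limma-trend and 113 with limma-trend at that CPM; leaving out each fish gave 0 to 1. In johnny darter (28) they became 0 with no filter, 0 with robust estimation, 0 with 1 surrogate variable, 5 at a CPM of at least 1, 16 at a CPM of at least 5, 621 with DESeq2, 469 with DESeq2 at a CPM of at least 1, 1 with limma-voom, 28 with limma-trend (19 shared) and 23 with limma-trend at a CPM of at least 1 (12 shared); leaving out each fish gave 0 to 1. RLE and upper quartile normalization left the counts of all 4 species within 1.5 times, and 27 of the 28 johnny darter genes were called under each.

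The share of variance explained on the 1000 most variable genes was 9.36% in greenside darter and 10.1% in johnny darter, past the threshold in neither, and on log2(TPM + 1) it was 25.2% in fantail darter, still past it; leaving out each fish gave 9.88% to 10.4% in rainbow, 14.8% to 17.6% in fantail, 11.7% to 13.4% in greenside and 11.4% to 12.04% in johnny darter, with no call changed. The difference in spread on the 1000 most variable genes was -4.40 in fantail and 4.16 in greenside darter, past the threshold in neither (adjusted p = 0.42 for both, permutation tests). On log2(TPM + 1) it was 12.03, reversed, in fantail and 0.73 in greenside darter. Leaving out each fish gave 1.64 to 11.3 in rainbow, -56.0 to -37.8 in fantail, 46.2 to 68.3 in greenside and 6.24 to 24.01 in johnny darter. The difference in the share of counts was 1.68 points for the 10 most abundant genes in greenside darter (adjusted p = 0.074, exact permutation test); leaving out each fish gave -0.98 to -0.15 in rainbow, -8.93 to -7.04 in fantail, 2.198 to 3.22 in greenside and -2.13 to -1.29 in johnny darter, the last passing the threshold without downstream fish 2.

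Replicate numbers are shared between sites. Correlations of same-numbered fish, as deviations from their site means, were -0.035 to 0.056, with none above 0.1. In rainbow darter, 3 of 6 fish per site correlated best with their own number. In each other species it was 0 or 1 fish per site. Whether the rainbow darter count exceeds chance was not tested, so a weak pairing there stays open. With the replicate block, 0 genes were called in rainbow, fantail, greenside and johnny darter. Site explained 17.2%, 27.004%, 20.9% and 19.7% of the variance left after the mean of each replicate number was subtracted. These shares have a smaller base and cannot be set against those without the block. Only 32 splits exist within numbers. Fantail and johnny darter gave the smallest p possible (0.031, adjusted 0.062), which cannot test stability. Greenside darter lost its call even unadjusted (permutation p = 0.062, adjusted 0.083). The planned tests of gene lists and species agreement need gene names and were not run. Each of the 3 named genes kept its direction under every alternative that tested it and lost its call under 14 to 17 of 24 or 25. Complete separation of the sites was a condition for naming them, so the kept direction is no evidence of stability. Leaving out each fish gave log2 fold changes of 2.08 to 2.34 (edgeR adjusted p = 0.059 to 0.099) for TRINITY_DN13054_c2_g1 and 2.15 to 2.51 (adjusted p = 0.029 to 0.11) for TRINITY_DN3173_c0_g3, and adjusted p of 0.041 to 0.21 for TRINITY_DN5041_c8_g1, listed at 0 downstream.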

Other observations

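Tests of genes at 0 at one site, of uneven detection and of depth, and the fish left out at a CPM of at least 1, were chosen after seeing the data. Of genes reaching 500 TPM in at least 3 fish and below 5 TPM in at least 3 others of the same species, there were 2 in rainbow, 3 in fantail, 4 in greenside and 2 in johnny darter. None of these 11 genes separated the sites.

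In johnny darter 28 genes were called for the real sites and at most 14 for another split, so 1 of 25 drawn splits, the real one, gave as many. Chance can be excluded only at that share, which is the smallest that 25 splits can give and is not adjusted over 4 species, and the real count fell to 0 or 1 without any 1 fish. It cannot be excluded in rainbow darter, where 3 of 25 splits gave as many as the real 1 gene and the highest other gave 8; at an unadjusted p under 0.05, 4 of 25 gave as many as the real 3041. With 0 genes in fantail and greenside darter, all 25 splits gave as many by construction (highest other 0 and 1), which says nothing about chance. At an unadjusted p under 0.05 the real sites gave the most genes of the 25 splits in both: 15432 against at most 13675 (median 2112) in fantail and 8174 against at most 4149 (median 2324) in greenside darter.

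In fantail darter, 2129 genes were called at a CPM of at least 1, and 1 of 60 drawn splits, the real one, gave as many, the highest other giving 11. Chance can be excluded only at that share, the smallest that 60 splits can give and not adjusted over species. At an unadjusted p under 0.05 the gap was narrower, with 11979 genes for the real sites and 9373 for the highest other split. Lower depth downstream would give fewer detected genes, yet downstream fish 5 and 6, the shallowest libraries at 41.8 and 40.9 M, listed 193731 and 205018 genes above 0, more than the highest upstream fish (180907), which argues against depth for detection. For the called genes, which ran both ways at a CPM of at least 5 (1541 higher, 1506 lower), its part stays open: 18.7% of genes were called at a CPM of at least 5 and 5.33% at a CPM of at least 1, but the percent of genes at an unadjusted p under 0.05 rose with this filter in all 4 species, so the comparison says nothing about depth. The share of counts in the 100 most abundant genes cannot be told apart from site: with it as a covariate 0 genes were called, and it correlates with site itself (r = -0.81). The influence of upstream fish 2 and 5 stays open too, since 0 genes were called without both but also in the median of the other 14 pairs of upstream fish, which saturates the test; at an unadjusted p under 0.05 there were 6943 genes without both, the fewest of the 15 pairs (others at least 7381, median 9385.5). The count was 0 to 4 without upstream fish 2, 4 or 5 or downstream fish 2, 4, 5 or 6, 4178 without downstream fish 1 and 3641 without downstream fish 3, and an effect of the site itself is untested.

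Some genes were above 0 in all 6 fish of a site and at 0 in all 6 of the other: 48 in rainbow, 216 in fantail (210 seen downstream), 120 in greenside (114 seen upstream) and 71 in johnny darter (28 seen downstream). Over all splits into 6 and 6, with the real one counted, as many arose in 57 in rainbow and 1 in fantail darter (highest other 109 and 170). In greenside and johnny darter, 2 and 1 splits did (highest other 128 and 62). The unadjusted p was 0.0022 in fantail, 0.0043 in greenside and 0.0022 in johnny darter (exact permutation tests). Chance can be excluded there only at those values, which are not adjusted over species or over the definitions chosen after seeing the data. Another greenside split gave more genes than the real one. With a mean of at least 1 TPM, 1 split gave as many in fantail (17 genes, highest other 10) and johnny darter (12 genes, highest other 8). In greenside darter 35 did (6 genes, highest other 11, p = 0.076, exact permutation test). In rainbow darter 52 did (4 genes, highest other 8, p = 0.11, exact permutation test). A further definition asked that the lowest of 6 fish reach 1 TPM and at least 20 times the highest of the other 6. By it there were 0 genes in fantail and 0 in greenside darter, which leaves nothing to test. There was 1 in johnny darter and 1 in rainbow darter, where chance cannot be excluded (p = 0.13 and 0.071, exact permutation tests). The rainbow darter gene called by edgeR, TRINITY_DN5041_c8_g1, meets this definition. An uneven number of detected genes is argued against in johnny darter, where 1 of 294 splits at least 80% as uneven gave as many, and 1 of 256 at least as uneven. It cannot be told apart from site in fantail darter (1 of 23, with only 2 splits at least as uneven) or greenside darter (2 of 7, with only 1 such split), where most of these genes were seen at the site with more detected genes. A response of the liver, a difference between the fish living at each site and the sex of the fish may each contribute, and none was tested. Within every species the libraries of each site held an unbroken run of index numbers. If libraries were handled in that order, handling cannot be told apart from site.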
